A study of Rattus norvegicus with 6 samples.

How the data were processed

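Hippocampi of rats were dissected 2 months after whole-brain irradiation with 20 Gy or without it, minced, digested with enzymes, passed through strainers, cleared of red cells by lysis and of dead cells with magnetic beads, and loaded on the Chromium 3′ v3 platform, in which each cell's transcripts carry a cell barcode and a unique molecular identifier (UMI). The labels name 3 control and 3 irradiated samples, all from male rats, and no sorting of cells. The deposited matrix holds UMI counts, whole numbers up to 6655, for 30452 genes and 58078 cell barcodes. The values are not scaled, which does not show whether reads were drawn to a common depth. Per the file headers it was written by Cell Ranger 7.0.0. Whether reads in introns were counted, whether libraries were brought to a common depth when they were joined, and the annotation version are not given in the sources used here. Per the labels the genome build is mm10, a mouse build, while every gene identifier in the matrix is a rat Ensembl identifier. Gene symbols were those of the deposited feature table; 7092 genes had an identifier only and were named by it. A gene name table for the rat assembly GRCr8 held 17157 of the symbols. All chromosome positions were left out, since the annotation behind the counts is unknown.

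Each barcode ends in a number from 1 to 6 that marks its library. Nothing in the sources used here ties these numbers to the 6 labelled samples, so 0 libraries were assigned to a group. No condition was inferred from the order, the size or the values of a library. The planned comparisons of irradiated with control samples (numbers of cells per class, genes and gene lists within a class, genes in the whole suspension, and the response between classes) were therefore not run. In their place, as fixed for this case before the data were examined, cell classes are described over the pooled matrix as 1 sample, and values per library are given with no group. Libraries are not treated as replicates of a condition, cells are not replicates, and no p-value or standard error was computed from them; Dixon's test for a library that stands apart was applied to the 6 libraries for Y-linked genes only.

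Barcodes with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrial genes were kept, which left 48704; 9227 exceeded the mitochondrial limit and 177 had too few UMIs or genes, some of them failing on both counts. Doublets were scored within each library against simulated sums of 2 cells, by the share of simulated doublets among 30 nearest neighbours, and the highest-scoring 0.8% of barcodes per 1000 barcodes of the library were removed. This removed 3904 barcodes, 8.02% of those that passed, and left 44800 cells with a median of 4944 UMIs and 1886 genes. In a test on simulated data, 275 made doublets of 2 different classes were added to library 1. Of these, 52.4% fell in the highest 8% of scores and 38.9% among the 275 highest, so doublets were removed incompletely. The cut used removed 350 of the 5857 passing barcodes of library 1, a smaller part than 8%. RNA of other cells in the droplets was neither estimated nor removed, so values within a class include any that was there. Counts were scaled to 10000 per cell and log-transformed. Cells were clustered by the Leiden method at resolution 1.0 on a graph of 15 nearest neighbours from 30 principal components of 2000 variable genes, with no alignment of libraries, which gave 29 clusters. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, python-igraph 0.11.9 and leidenalg 0.10.2, and plots used matplotlib 3.10.9.

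Markers of 20 cell classes and 27 gene lists were fixed before the data were examined, as were the filters, the clustering settings and the marker shares of cycling and neuroblast cells. The alternatives for class shares were fixed then too, except those that left out a library, lifted the mitochondrial limit or equalized cells per library. A cluster took the name of a class, written "X-like", when the class's markers averaged a log2 ratio of at least 1 over the median of clusters, led the next class by at least 1, and at least 3 of the markers passed a log2 ratio of 1 and were found in at least 10% of cells. The ratios had 10 CPM added to both sides. Clusters in which these conditions failed, or whose leading genes belonged to another class, kept a number, or were called cycling cells where at least 10 cycling markers passed. The details of this naming rule, cycling as a state rather than a class, and the share of doublets removed were settled after the data had been examined.

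Counts were summed over the cells of a class and expressed as CPM, the usual scaling of counts to a common total per class. For each list, the log2 ratio of the class's CPM to the median CPM of 12 classes and clusters, with 10 CPM added to both, was taken for each gene, and the median over genes is given. Only classes and clusters of at least 100 cells entered, except cluster 11, whose scores for microglia and red cells were equal and which entered in an alternative, and fixed cell markers and genes under 5 CPM were left out of the lists. Each median is set beside 10000 random lists matched on expression in 20 bins. Its percentile among them is a description and not a p-value. For values per library, the mean over the list of each gene's log2 difference from its median over the libraries was taken, with 1 CPM added, in classes with at least 20 cells in the library. With a doubling put into 30 simulated list members the median over classes gave 0.77 instead of 1.0 on the log2 scale, since the added 10 CPM lower it, and the range over libraries gave 0.97. These list summaries, all their alternatives and the choice of list and class pairs were made after the data had been examined.

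Shares of cells carry exact Clopper-Pearson 95% intervals, and summed counts exact Poisson 95% intervals. Both cover counting error only, not the difference between animals. A share of 0 is given with the limit that 3 counts would set. For cycling and neuroblast markers every cell was thinned at random to 1000 UMIs, which left out 1742 cells with fewer. The planned rule for named genes took the genes with the largest changes between irradiated and control samples and could not be applied. Its fixed genes Cdkn1a, Mdm2, Gfap, P2ry12, Cd74, Mbp and Dcx are given, Cldn5 was not analysed here because the feature table gives no such symbol, and every other named gene was chosen after its values were seen. Alternatives tried were stricter and looser cell filters, no removal of doublets, a coarser clustering, classes from each cell's highest marker score, equal numbers of cells per library, leaving out each library in turn, thinned counts, CPM without mitochondrial genes, cluster 11 among the classes compared and another added value.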

Results

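Whole-brain irradiation is used against brain tumours and can be followed by a loss of memory, and the hippocampus holds dividing progenitors of neurons. The labels set 3 control rats beside 3 rats irradiated with 20 Gy 2 months earlier, which asks how the cells of the hippocampus differ at that time. The matrix held 329205505 UMIs in 6 libraries, 0 of which could be tied to a labelled sample. No comparison of irradiated with control animals was therefore made. Library 1 held 7479 barcodes and 46853113 UMIs, library 2 held 10448 and 58560418, and library 3 held 11931 and 51442539. Library 4 held 10429 barcodes and 62094407 UMIs, library 5 held 10069 and 59528067, and library 6 held 7722 and 50726961. The libraries gave 5507, 8401, 9563, 8014, 7945 and 5370 kept cells, from library 1 to 6, with median depths of 6287, 4906, 4150, 5066, 4943 and 6414 UMIs.

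The kept cells were mostly microglia-like and astrocyte-like, with few cells of the neuronal line. Microglia, the resident macrophages of the brain, made up 47.9% of 44800 cells (95% interval 47.5 to 48.4%), and astrocyte-like cells 26.5% (26.1 to 26.9%). Cluster 1, a myeloid population that met the rule for no class, made up 14.1% (13.8 to 14.5%), and cluster 13, related to it, 1.56% (1.45 to 1.68%). Cluster 1 kept a number because 2 classes were close. It scored 1.71 for border macrophages, with 5 of 9 markers passing, and 1.53 for microglia, with 8 of 14. Cluster 13 scored 1.42 and 1.41 for the same classes. T or NK cell-like cells made up 2.00% (1.87 to 2.13%), mature oligodendrocyte-like cells 1.86% (1.73 to 1.99%) and border macrophage-like cells 1.46% (1.35 to 1.58%). Neutrophil-like cells reached 0.516%, cycling cells 0.504%, oligodendrocyte precursor-like cells 0.440%, neuroblast-like cells 0.292%, endothelial-like cells 0.270% and B cell-like cells 0.123%. In all, 22 clusters were named in 11 classes, and 7 clusters with 8116 cells, 18.1% of all, kept a number. No cluster met the rule for mature neurons; cluster 27, with 42 cells, was led by Pcp4, Ndnf and Reln. Cluster 11 carried 13 of 14 microglia markers, with the haemoglobin genes that led it found in few of its 855 cells (Hbb-b1 in 2.69%), clusters 23 and 28 microglial genes beside those of astrocytes or oligodendrocytes, and cluster 24, with Rgs5, Vtn and Dcn among its leading genes, 9 of 10 markers of fibroblasts and 9 of 13 of mural cells. With a mitochondrial limit of 10% the astrocyte-like share was 12.2%, the mature oligodendrocyte-like share 0.925% and the precursor-like share 0.270%. With each cell named by its highest marker score, cycling cells were 1.60%, neuroblast-like cells 1.05%, precursor-like cells 1.47%, endothelial-like cells 1.60%, neutrophil-like cells 1.79% and B cell-like cells 2.76%. In that setting the share of border macrophage-like cells was 8.52%, and at the coarser clustering they formed no cluster of their own (0%).

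Shares varied widely over the libraries. Microglia-like cells were 80.6%, 77.6%, 73.9%, 20.4%, 17.2% and 8.36% of cells from library 1 to 6, with a median of 47.2%. Astrocyte-like cells were 9.99%, 15.7%, 15.9%, 50.3%, 30.2% and 38.0% in the same order. Clusters 1 and 13 together were 0.0363%, 0.0119%, 0.0105%, 21.3%, 36.7% and 44.9%. These clusters scored nearly as high for microglia as for border macrophages and are counted in neither share. Border macrophage-like cells numbered 3, 18, 34, 171, 305 and 124, and the share of border macrophage-like cells over all libraries was 0.9497% without library 5. Mature oligodendrocyte-like cells were 1.198%, 1.77%, 2.06%, 0.986%, 3.98% and 0.466%. T or NK cell-like cells ranged from 0.833% to 3.77%, with a median of 1.62%. Neutrophil-like cells ranged from 0.218% to 1.203%, and their share of all cells was 0.329% without library 3. Endothelial-like cells ranged from 0.01248% to 0.705%, and their share of all cells was 0.176% without library 5. No spread within a condition can be given for these values.

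**Figure D1:**
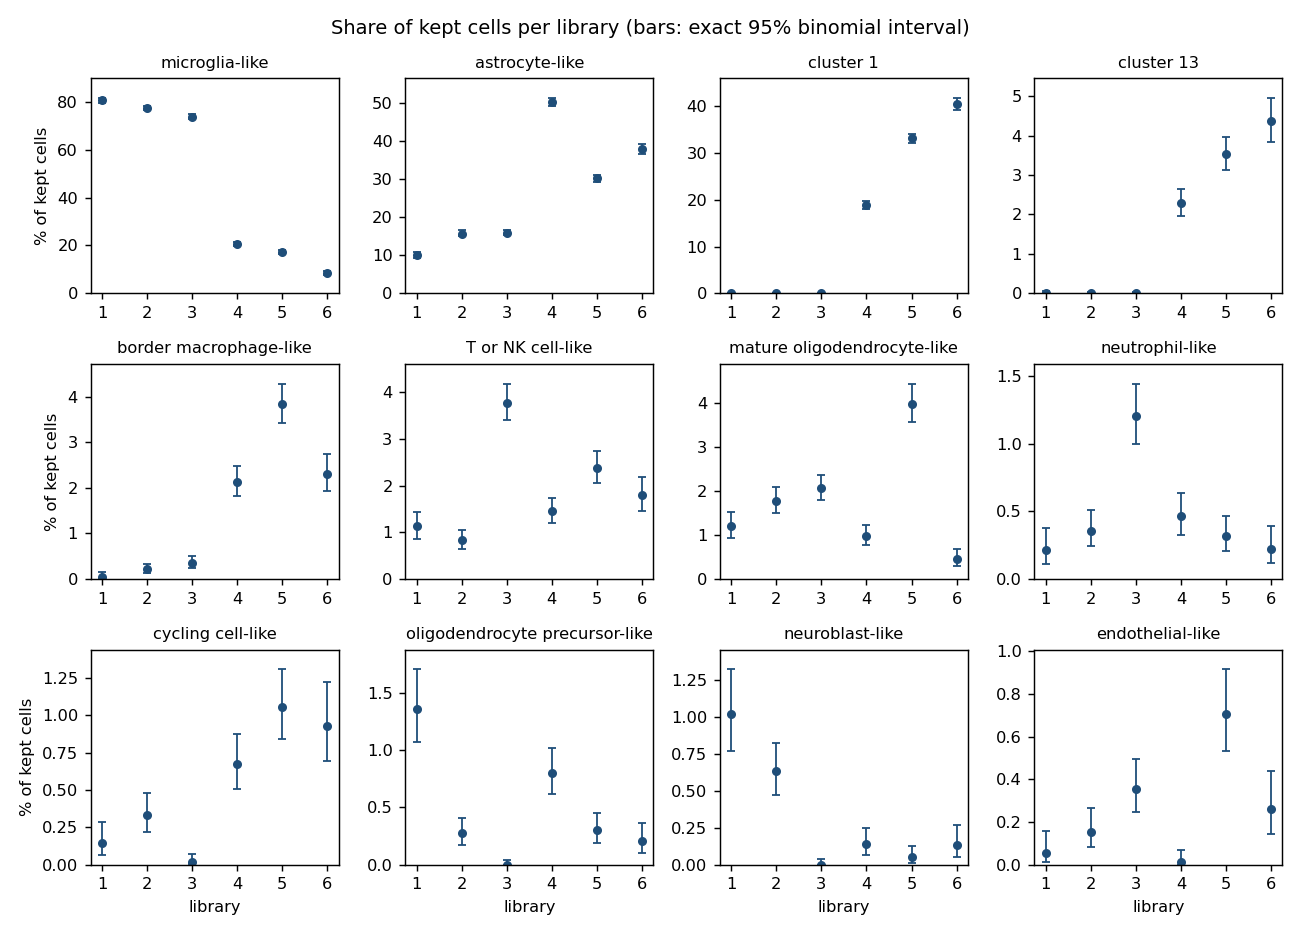
Share of kept cells (vertical axes, percent) in each of the 6 libraries (horizontal axes) for the named classes with at least 100 cells and for clusters 1 and 13. Points are shares and bars exact 95% binomial intervals, which cover counting error only; microglia-like cells ranged from 8.36% to 80.6%.

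The microglia-like cells carried the genes of resident microglia, and clusters 1 and 13 shared some of these genes while differing in others. C1qa, which encodes a chain of complement C1q, stood at 6909 CPM in microglia-like cells (6894 to 6924) and at 3986 CPM in cluster 1 (3965 to 4006). The microglial receptor gene P2ry12 was at 831 CPM in microglia-like cells and 71.5 CPM in cluster 1, and Tmem119 at 1090.0 and 108 CPM. Sall1, a transcription factor of microglial identity, was at 222 and 6.36 CPM. Lyz2, the lysozyme gene of phagocytes, was at 15914 CPM in cluster 1 and 1337 CPM in microglia-like cells. Clec7a, a receptor for fungal glucans, was at 712 and 5.74 CPM, the lysosomal glycoprotein gene Cd68 at 693 and 123 CPM, and the galectin gene Lgals3 at 585 and 13.7 CPM. Ms4a7, a macrophage marker, was at 55.7 CPM in cluster 1 and 0.450 CPM in microglia-like cells, while the monocyte receptor gene Ccr2 was at 0.0563 CPM (0.00682 to 0.203) and 0.329 CPM. These genes helped to form the clusters, so their differences describe the clusters and are not tests.

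Cluster 13 differed from cluster 1 in genes induced by type I interferon. Ifit3 was at 476 CPM in cluster 13 and 28.2 CPM in cluster 1, Irf7, which encodes a transcription factor that amplifies interferon production, at 518 and 75.7 CPM, and the antiviral GTPase gene Mx1 at 837 and 101 CPM. Over the interferon list, all 33 measured members in cluster 13 lay above the median of the 12 classes, with a median log2 ratio of 2.08 at percentile 100 of random lists. Neutrophil-like cells had 27 of 33 members above, with a median of 0.67, and border macrophage-like cells 29, with 0.43. Cycling cells had 30 above (0.39), cluster 1 24 (0.18) and T or NK cell-like cells 17 (0.01). Microglia-like cells had 5 members above, with a median of -0.26 that was -0.04 without library 3 and -0.09 without library 5, where it no longer lay in the outer 5% of random lists. Within the 6 libraries the microglial median ran from -0.046 to 0.42, above 0 in 2 and below 0 in 3, so the pooled value does not describe the single libraries. Astrocyte-like cells stood at -0.73 (-1.061 to 0 within libraries), neuroblast-like cells at -1.03 (-0.187 and -0.103 in the 2 libraries measured) and mature oligodendrocyte-like cells at -1.41 (-1.683 to -0.589), the last with 0 members above. Over all lists, 163 pooled medians lay in the outer 5% of random lists; 47 of these were outside the range of the medians within libraries, where only classes with at least 20 cells are compared, and 23 had the other sign in at least 1 library. Interferon genes were among the leading genes of cluster 13 and of the neutrophil-like cluster.

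Among the 12 classes and clusters compared by list, border macrophage-like cells had the highest values of antigen presentation by MHC class II; the 55 B cell-like cells, too few for that comparison, stood higher in both class II genes given next, with Cd74 at 11897 CPM and RT1-Da at 4339 CPM. Cd74, the invariant chain of MHC class II, was at 10811 CPM there (10705 to 10916), 518 CPM in microglia-like cells and 306 CPM in cluster 1. RT1-Da, a rat MHC class II chain gene, was at 3229 CPM in border macrophage-like cells and 111 CPM in microglia-like cells. Mrc1, a mannose receptor gene of border macrophages, was at 120 CPM (109 to 131) against 30.2 CPM in cluster 1. Clec10a, another fixed marker of border macrophages, differed less, at 404 against 328 CPM. All 11 measured class II members lay above the median of classes in border macrophage-like cells (2.503), in microglia-like cells (1.103) and in cluster 13 (0.71). With each cell named by its highest marker score the microglial median was -0.43 and that of border macrophages 0.50. With a mitochondrial limit of 10% the same medians were 0.27 and 1.48, and with doublets kept the median of MHC class II presentation in border macrophage-like cells was 1.76. MHC class I genes had all 13 members above in T or NK cell-like cells (0.95) and in cluster 13 (0.82), and 0 above in mature oligodendrocyte-like cells (-1.91).

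Inflammatory genes stood higher in the pooled macrophage-like classes than in the glia of neural origin, while lysosomal genes did not part every myeloid class from these glia. Cytokines and targets of NF-kB, a transcription factor of inflammation, had 24 of 25 members above in border macrophage-like cells (median 1.12) and in microglia-like cells (0.49), and 22 above in both cluster 13 (0.95) and cluster 1 (0.79), against 3 in astrocyte-like cells (-0.83). Within libraries the NF-kB median ran from 0.169 to 1.729 in microglia-like cells and from 0.339 to 0.831 in cluster 1. Cxcl2, a chemokine gene for neutrophils, was at 2121 CPM in cluster 1 and 227 CPM in microglia-like cells, and the interleukin gene Il1b at 459 and 84.2 CPM, while Tnf was at 185 and 234 CPM. Cluster 6, with 2709 of 2712 cells from library 3, had Cxcl2 at 1136 CPM and Tnf at 743 CPM. The pooled microglial values of Cxcl2 and Tnf thus rest in part on library 3. Disease-associated microglia genes had 13 of 19 members above in cluster 1 (0.98) and 15 in border macrophage-like cells (0.98). Within libraries the median of this list was from 0.293 to 0.47 in cluster 1, measured in 3 libraries, and from 0 to 0.656 in microglia-like cells, measured in 6, so the pooled values do not show that cluster 1 stood higher within a library. Among them Gpnmb was at 154 CPM in cluster 1 and 30.8 CPM in microglia-like cells, and Itgax, an integrin gene, at 125 and 3.06 CPM. The same list stood at 0.10 in microglia-like cells, a value that changed sign with a mitochondrial limit of 10% (-0.08), was 0 without library 1, 2, 3 or 5 and with cluster 11 among the classes compared, and 0.06 without library 4. In cluster 1 it was 0.39 with that limit. Apoe, which encodes a lipid carrier, went the other way, with 3698 CPM in cluster 1, 16331 CPM in microglia-like cells and 38670.0 CPM in astrocyte-like cells. Complement genes had 10 of 14 members above in microglia-like cells (1.31), and lysosomal genes 25 of 26 (1.25), with 14 in astrocyte-like cells (0.07) and 10 in neutrophil-like cells (-0.075). Senescence and secretory genes had 13 of 17 members above in border macrophage-like cells (0.49) and in cluster 13 (0.40), 14 in cluster 1 (0.27) and 11 in cycling cells (0.41), against 1 in mature oligodendrocyte-like cells (-0.36). Within libraries the medians of this list were lower, from -0.041 to 0.443 in border macrophage-like cells, 0.123 to 0.386 in cluster 13 and -0.001 to 0.15 in cycling cells. In cluster 1 they ran from 0.277 to 0.37. Homeostatic microglia genes outside the fixed markers had 11 of 13 members above in microglia-like cells (2.02) and 10 in cycling cells (1.75). Immediate early and dissociation genes, which rise while tissue is taken apart, had all 24 members above in cluster 1 (0.96) and cluster 13 (0.79), 23 in border macrophage-like cells (1.096) and 0 in astrocyte-like cells (-2.99). In microglia-like cells 16 lay above (0.22), a median that changed sign with a mitochondrial limit of 10% (-0.13), with highest marker scores (-0.08) and without library 3 (-0.001), and was 0 without library 1, 2 or 5.

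**Figure D2:**
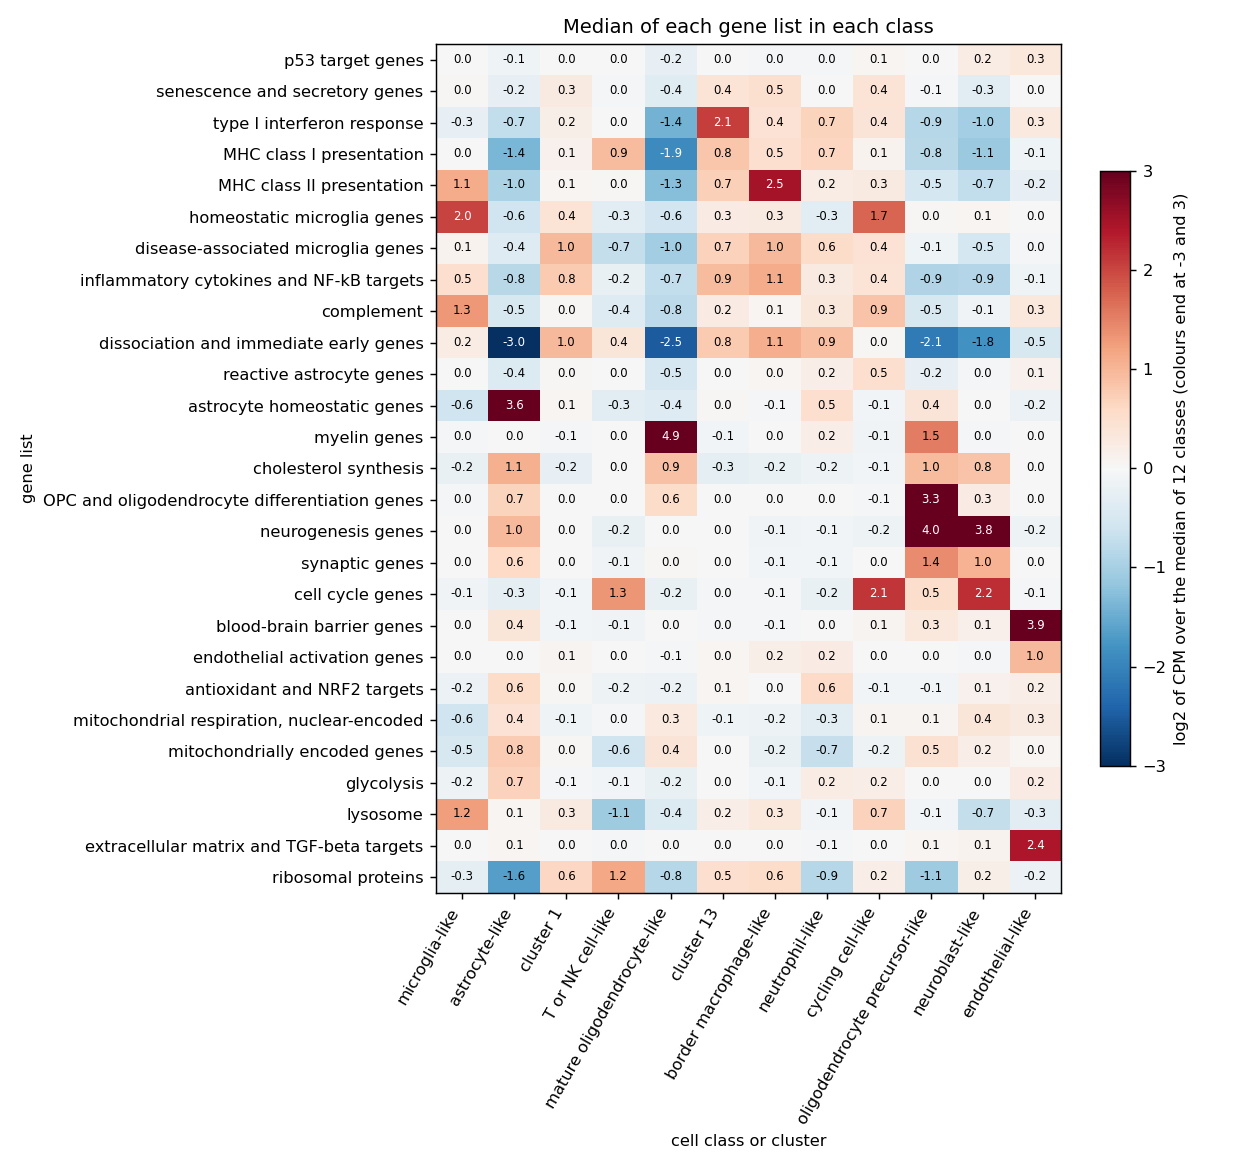
Median over each of the 27 gene lists (vertical axis) of the log2 ratio of CPM in a class or cluster (horizontal axis) to the median of 12 classes, printed in each cell. The interferon list had its highest value in cluster 13 (2.08) and the MHC class II list in border macrophage-like cells (2.503); clusters formed partly on the same genes.

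Astrocyte-like cells led in genes of sterol synthesis and energy metabolism. Cholesterol synthesis genes had 20 of 22 members above the median of classes there (median 1.08), 19 in mature oligodendrocyte-like cells (0.87) and in neuroblast-like cells (0.85), 20 in precursor-like cells (0.95), and 5 in microglia-like cells (-0.22). The precursor value was 0.22 with each cell named by its highest marker score and left the outer 5% of random lists without library 2 (0.80), and the microglial value left the outer 5% of random lists without library 1, 2, 4, 5 or 6, the nearest to 0 being -0.12 without library 1, and with cluster 11 among the classes compared (-0.092). Within libraries the neuroblast median was 0.298 and 0.504 in the 2 libraries measured. The precursor median ran from -0.185 to 1.25 over 4 libraries, below 0 in 1. Hmgcs1, an enzyme of the mevalonate pathway, was at 373 CPM in astrocyte-like cells, 188 CPM in mature oligodendrocyte-like cells and 45.4 CPM in microglia-like cells, and squalene epoxidase, Sqle, at 174, 155 and 25.6 CPM. Glycolysis genes had 16 of 19 members above in astrocyte-like cells (0.68), and Aldoc, an aldolase gene, stood at 5164 CPM against 253 CPM in microglia-like cells. Nuclear genes of mitochondrial respiration had 30 of 32 members above in astrocyte-like cells (0.43) and 1 in microglia-like cells (-0.59), and mitochondrially encoded genes all 13 (0.75) and 1 (-0.48). The last value was -0.35 without library 3 and -0.41 without library 4, no longer in the outer 5% of random lists. Antioxidant genes and targets of NRF2, a regulator of the oxidative stress response, had 14 of 21 members above in astrocyte-like cells (0.56) and 16 in neutrophil-like cells (0.58, and 0.11 with each cell named by its highest marker score). Astrocyte homeostatic genes outside the markers had all 13 members above (3.56). Reactive astrocyte genes had 9 of 21 members above in astrocyte-like cells, with a median of -0.41, while Gfap, the intermediate filament gene of astrocytes, was at 1522 CPM (1514 to 1531). Ribosomal protein genes had 1 of 82 above in astrocyte-like cells (-1.64), and 81 in T or NK cell-like cells (1.16).

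Cells of the oligodendrocyte, neuronal and vessel lines were few, and lists of their kind stood high in them. The neurogenesis and synaptic lists did not set neuroblast-like cells above precursor-like cells. Mbp, myelin basic protein, was at 6256 CPM in mature oligodendrocyte-like cells (6185 to 6328), and all 11 myelin genes outside the markers lay above the median of classes there (median 4.88), with 9 above in precursor-like cells (1.54). Genes of precursors and their differentiation had 6 of 7 members above in precursor-like cells (3.31). The precursor-like cluster also scored 4.12 for newly formed oligodendrocytes, with 8 of 8 markers passing, against 5.31 for precursors. Its values, those of myelin and cholesterol synthesis genes included, may therefore not describe precursors alone. Neurogenesis genes had all 5 members above in precursor-like cells (3.96) and neuroblast-like cells (3.85), and synaptic genes all 21 in the same classes (1.41 and 1.04). Within libraries the neurogenesis median ran from 1.184 to 3.619 in precursor-like cells and from 0.923 to 2.554 in neuroblast-like cells. The synaptic median ran from 0.404 to 1.489 and from 0.471 to 0.93 in the same order. Dcx, a microtubule-associated protein of migrating neuroblasts, was at 341 CPM in neuroblast-like cells (311 to 372) and 0.212 CPM in mature oligodendrocyte-like cells. Endothelial-like cells had all 18 blood-brain barrier genes above (3.89), 10 of 16 endothelial activation genes (0.98) and 16 of 18 genes of extracellular matrix and TGF-beta response (2.43). The haemoglobin genes Hbb-b1 and Hba-a2, also among the leading genes of their cluster, were found in 14.0% and 4.96% of its cells. Neuroblast-like cells numbered 56, 53, 0, 11, 4 and 7 from library 1 to 6, and precursor-like cells 75, 23, 0, 64, 24 and 11. For library 3, 0 of 9563 cells allow a share of up to 0.0314% in either cluster. This limit covers counting only. Libraries were not aligned and library 3 largely filled clusters 4, 6 and 8, so such cells may lie in other clusters. By markers alone, 0 of 9121 thinned cells of library 3 carried at least 2 neuroblast markers, while precursors were not counted in this way. The share of neuroblast-like cells over all libraries was 0.191% without library 1.

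At equal depth, the share of cells with cycling markers was highest in cycling, neuroblast-like and T or NK cell-like cells, among the classes measured. This share was not taken for precursor-like cells. In these, 16 of 19 cell cycle genes lay above the median of classes (0.53, percentile 75.4 of random lists). Cycling cells, with Mki67, Top2a and Cenpf among their leading genes, also carried all 14 measured microglia markers, while the immunoglobulin gene Ighm was found in 30.1% of them and AABR07060872.1, which led the B cell-like cluster too, in 3.54%. Mki67 stood at 1488 CPM there, 312 CPM in neuroblast-like cells, 253 CPM in T or NK cell-like cells and 1.70 CPM in mature oligodendrocyte-like cells. All 19 cell cycle genes outside the markers lay above the median of classes in neuroblast-like (median 2.21), cycling (2.14) and T or NK cell-like cells (1.33). At 1000 UMIs per cell, 420 of 43058 cells carried at least 2 cycling markers, a share of 0.975% (0.885 to 1.07%), and without thinning 1599 of 44800 did, a share of 3.57%. Of these 1599, 512 were microglia-like and 343 astrocyte-like, 2.38% and 2.89% of their classes, against 2.52% of mature oligodendrocyte-like cells. The thinned share was 28.2% in neuroblast-like cells (20.7 to 36.8%) and 10.6% in T or NK cell-like cells (8.61 to 12.8%). It was 0.336% in cluster 1 (0.208 to 0.513%), 0.165% in microglia-like cells (0.115 to 0.230%), 0.149% in astrocyte-like cells (0.0849 to 0.241%) and 0.120% in mature oligodendrocyte-like cells (1 of 831 cells, 0.00305 to 0.669%). With at least 3 markers the thinned share was 14.5% in neuroblast-like cells, 8.97% in T or NK cell-like cells, 0.0640% in cluster 1 and 0.0189% in microglia-like cells. Of 10771 astrocyte-like cells 0 passed, which allows up to 0.0279%. Of 222 thinned cycling cells 199 passed, and since these cells carried microglia markers and had been placed in their own cluster, the low share in microglia-like cells does not measure how often microglia divide. Over all thinned cells, the share from library 1 to 6 was 0.726%, 0.737%, 0.636%, 1.11%, 1.43% and 1.35%. At least 2 neuroblast markers were found in 71 thinned cells, 0.165% (0.129 to 0.208%), in 0.234% without thinning, and in 0 of 21171 thinned microglia-like cells, which allows up to 0.0142% of them to pass at this depth, where 54.2% of neuroblast-like cells did. By library this was 0.614%, 0.331%, 0%, 0.0912%, 0.0393% and 0.0196%, and over all cells 0.101% without library 1.

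The lymphoid cells were mostly cytotoxic T or NK cell-like cells. Ccl5, a chemokine gene, was at 14699 CPM over the 894 T or NK cell-like cells, Gzmk, a granzyme gene, at 1609 CPM and Cd8a at 759.9 CPM (735 to 786). Their 4 clusters were led by Ccl5, Nkg7 and Cd8a, by Gzma and Gzmk, by genes that included Ccr7, a chemokine receptor gene, and Tcf7, a T cell transcription factor gene, and by cytotoxic and cell cycle genes. Neutrophil-like cells were led by S100a8 and S100a9, which encode calprotectin, beside the interferon genes Slfn4 and Ifit3. Lysosomal genes had 1 of 26 members above in T or NK cell-like cells (-1.06).

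Targets of p53, the transcription factor that responds to DNA damage, had pooled medians near 0 in most classes, and their levels varied over the libraries. Over the 27 measured members the median log2 ratio was 0.02 in microglia-like cells, -0.13 in astrocyte-like cells, -0.24 in mature oligodendrocyte-like cells, 0.22 in neuroblast-like cells and 0.31 in endothelial-like cells. Within libraries the microglial median ran from 0 to 0.373, above 0 in 5 of 6, so the pooled value does not describe the single libraries. The astrocyte value left the outer 5% of random lists without library 1 (-0.05) or 2 (-0.03), the oligodendrocyte value without library 1 (-0.06), 2 (-0.08), 5 (-0.14) or 6 (-0.18), and the endothelial value without library 2 (0.23) or 6 (0.21). The microglial value entered it without library 2 (0.01) or 6 (0.01). With cluster 11 among the classes compared the medians were 0.032 in microglia-like cells, which entered it, and -0.012 in astrocyte-like and -0.135 in mature oligodendrocyte-like cells, which left it. Cdkn1a, the p53 target that arrests the cell cycle, was at 101 CPM in microglia-like cells (98.99 to 103), 32.2 CPM in astrocyte-like cells and 95.3 CPM in mature oligodendrocyte-like cells (86.7 to 105). From library 1 to 6 it was at 31.7, 19.4, 57.2, 204, 497 and 632 CPM in microglia-like cells, and at 2.30, 1.21, 2.33, 39.4, 46.0 and 44.7 CPM in astrocyte-like cells. In mature oligodendrocyte-like cells Cdkn1a was at 59.0, 44.7, 60.3, 122, 136 and 182 CPM. Mdm2, which encodes the ligase that degrades p53, ranged from 36.2 to 82.1 CPM in microglia-like cells, with a median of 49.3, and from 29.0 to 33.2 CPM in astrocyte-like cells. Phlda3, a p53 target that restrains AKT, ranged from 0.896 to 115 CPM in microglia-like cells, with a median of 29.2.

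Over the libraries, the p53 list gave -0.47, -0.56, -0.45, 0.33, 0.61 and 0.58 in microglia-like cells over 21 members, a range of 1.18, and -0.40, -0.52, -0.37, 0.33, 0.31 and 0.34 in astrocyte-like cells over 19 members, a range of 0.85. In mature oligodendrocyte-like cells its range of 0.73 lay at percentile 66.3 of random lists. The interferon list gave -0.38, -0.25, -1.25, 0.41, 0.39 and 0.47 in microglia-like cells, a range of 1.72 that was 0.85 without library 3, and a range of 1.49 in astrocyte-like cells that was 0.88 without it. Immediate early and dissociation genes gave -0.16, -0.20, 1.101, -0.60, 0.23 and 0.16 in microglia-like cells, a range of 1.70 that was 0.83 without library 3, and ranged by 1.06 in astrocyte-like cells (0.68 with a mitochondrial limit of 10%). Disease-associated genes ranged by 1.38 and NF-kB targets by 1.46 in microglia-like cells. Astrocyte homeostatic genes gave -0.39, -0.26, -0.80, 0.89, 0.29 and 0.27 in microglia-like cells, a range of 1.69, and myelin genes ranged by 1.62 there and by 0.09 in mature oligodendrocyte-like cells. The microglia-like cells came from different clusters in different libraries, so these values compare different clusters. Cluster 4 had 4299 of 4347 cells and cluster 6 had 2709 of 2712 cells from library 3. Clusters 2 and 3 held 1794 and 2523 such cells of library 1 and 3880 and 2452 of library 2. Cluster 5 held 107, 161, 8, 1428, 1137 and 434 from library 1 to 6, most of the microglia-like cells of libraries 4, 5 and 6. Among astrocyte-like cells, cluster 0 held 382, 872, 12, 2225, 1740 and 1334 from library 1 to 6. Cluster 8 had 1140 of 1158 cells from library 3, and cluster 9, with 6 of 13 mature oligodendrocyte markers as well, had 915 of 925 from library 4. The astrocyte values of libraries 3 and 4 thus also compare different clusters in part. Gfap ranged from 950.0 to 1793 CPM in astrocyte-like cells (median 1371), P2ry12 from 549 to 1161 CPM in microglia-like cells (median 692), Cd74 from 264 to 704 CPM there (median 583) and Mbp from 5704 to 7710.0 CPM in mature oligodendrocyte-like cells (median 5977). Dcx was at 344 and 343 CPM in neuroblast-like cells of libraries 1 and 2, where at least 20 such cells were found.

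**Figure D3:**
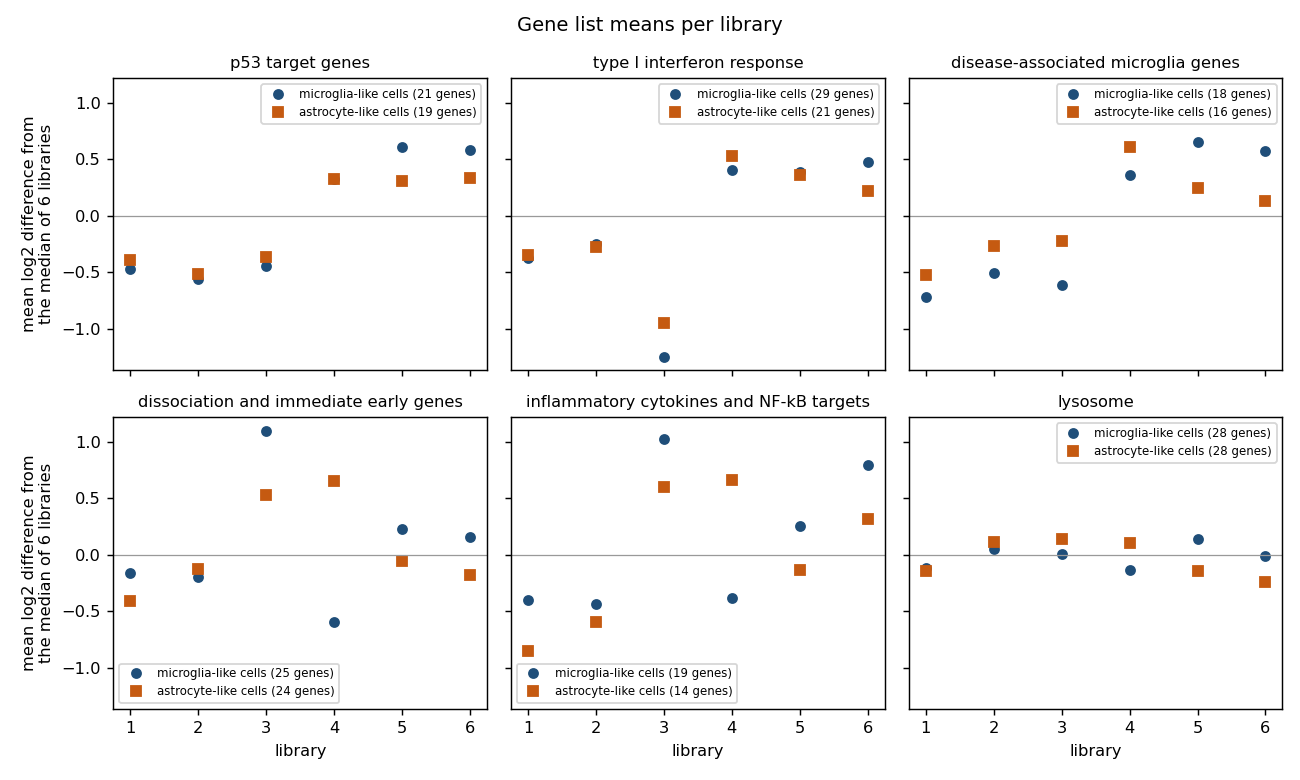
Mean over 6 gene lists of each gene's log2 difference from its median over libraries (vertical axes), in the 6 libraries (horizontal axes), for microglia-like (circles) and astrocyte-like cells (squares). Each point is 1 library with no group, and the p53 list in microglia-like cells lay between -0.56 and 0.61.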

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

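The tests of explanations in this part were chosen after the results were seen. All samples are labelled male, and library 3 held 0 UMIs of both Y-linked genes measured under their symbols, Eif2s3y, a translation factor gene, and Kdm5d, a histone demethylase gene. The other libraries held from 3007 to 4219 UMIs of Eif2s3y, at 62.9 to 67.9 CPM, and from 863 to 1667 UMIs of Kdm5d, at 18.4 to 26.9 CPM. The gap of library 3 to the next library was 0.926 of the whole range for Eif2s3y and 0.686 for Kdm5d, above the critical value of Dixon's test, which chance passes in about 1 in 20 groups. From library 1 to 6, 37.2%, 34.4%, 0%, 37.7%, 36.0% and 37.7% of barcodes carried a UMI of either gene. For no other measure was a library compared with the rest in this way, since the 6 libraries mix both conditions in an unknown order.

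Low depth of library 3 was excluded as the explanation, since at the lowest level of the other libraries 3238 UMIs of Eif2s3y would have been counted there. Processing that dropped many genes from library 3 was excluded as well: of 9645 genes at 5 CPM or more in each of the other libraries, 0.0518% (95% interval 0.0168 to 0.1209%) had 3 or fewer UMIs in library 3, namely Eif2s3y, Kdm5d, Ddx3, RGD1561730 and ENSRNOG00000060617. Chromosome positions were left out, so whether Ddx3, RGD1561730 and ENSRNOG00000060617 are Y-linked too was not determined. A loss confined to a few genes stays open. In library 3, 14 genes, these 5 included, were more than 8 times below the lowest of the other libraries and 11 more than 8 times above the highest, against 0 below and 0 or 1 above in each other library. Among the 14 was ENSRNOG00000062337, named after its values were seen, at 970 CPM against 18330 to 21560 CPM. So were AY172581.24, at 780 against 9940 to 12996 CPM, and AY172581.9, at 265 against 3413 to 5285 CPM, both named after their values were seen and counted as mitochondrial in the cell filter. The median mitochondrial share of library 3 was 4.6%, against 7.39% to 12.22% in the others, so a mitochondrial limit does not bear on library 3 as on the others. Whether processing or the animal set these genes apart was not tested. A female animal under a male label may also account for it, and stays open because the matrix held 0 genes named Xist, the transcript that would mark a second X chromosome. Genes with an identifier only were also nearly confined to library 3. ENSRNOG00000065796 had 1705 UMIs there and 3 to 5 in each other library, and ENSRNOG00000063866 had 1672 and 4 to 16. What these identifiers encode was not determined, so they do not decide the sex of the animal. The design names no difference in sex, so no biological explanation was tested.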

How the results depend on the processing

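Alternatives that left out a library, lifted the mitochondrial limit or equalized cells, the filters applied to marker shares, and every alternative for gene lists were chosen after the data were examined. Over 16 shares, 58 of 114 values under other settings stayed within the 95% interval and 56 moved, as did 56 of 96 with a library left out. Over 61 list medians, 541 of 574 values under other settings kept their place below, inside or above the middle 95% of random lists, 25 entered it, 3 left it and 5 reversed their sign. With a library left out these were 327, 26, 2 and 1 of 356. The sign was compared only for medians that lay outside the middle 95% in the main setting. Only 8 ranges over libraries were tried, all of which lay at percentile 100 of random lists in the main setting. All 80 of their values under other settings and all 48 with a library left out stayed outside the middle 95%. As these 8 were chosen after the data were examined, this does not show that other ranges would hold. The share of microglia-like cells was 63.6% with a mitochondrial limit of 10%, 41.4% with no limit, 49.2% with at least 1000 UMIs and 500 genes, 38.9% with classes from the highest marker score, 46.4% with equal numbers of cells per library and from 40.9% to 54.6% with each library left out. In the first 4 of these settings the share of astrocyte-like cells was 12.2%, 34.1%, 25.03% and 22.99%, and it ran from 21.3% to 29.3% over libraries left out. The share of mature oligodendrocyte-like cells was 0.925% and 2.39% with the 10% limit and none, 2.75% with highest scores and from 1.40% to 2.05% over libraries left out. The share of T or NK cell-like cells was 2.67% and 1.71% with the 10% limit and none, and from 1.51% to 2.26%. The share of cycling cell-like cells was 1.60% with highest scores and from 0.385% to 0.636%, and the share of neuroblast-like cells 1.05% and from 0.191% to 0.372%. The share of all unnamed clusters was 16.7% and 17.1% with the 10% limit and none, 19.6% both at resolution 0.5 and with equal numbers of cells, and from 13.4% to 22.4%. Leaving microglia-like cells out of the total raised the shares by construction, to 50.9% astrocyte-like, 3.57% mature oligodendrocyte-like, 3.83% T or NK cell-like, 0.969% cycling, 0.562% neuroblast-like and 34.8% unnamed. The share of cells with cycling cell markers was 3.57% without thinning, 0.657% with 3 markers, 1.104% with the 10% limit and from 0.878% to 1.07% over libraries left out; the share of cells with neuroblast markers was 0.234%, 0.111% with 3 markers and from 0.101% to 0.209%. In microglia-like cells, the median of disease-associated microglia genes reversed to -0.083 with the 10% limit and -0.048 with highest scores. The median of dissociation and immediate early genes in microglia-like cells reversed to -0.128 and -0.080 in these settings and to -0.001 without library 3, the others left out giving up to 0.23. The median of MHC class II presentation in microglia-like cells reversed to -0.43 with highest scores. For moves that neither thinning, stricter marker numbers nor a changed total brings by construction, the cause was not tested. At resolution 0.5 no border macrophage cluster formed, so its lists had no value there. No paired analysis was possible because barcodes could not be tied to samples. For the same reason the alternatives fixed beforehand for group tests were not run: other scaling or size factors, other tests, other filters on low counts, a block by sample number, TMM factors over class counts, exact permutation tests, thinning to the smallest sample, equal cells per sample, other list tests and prior counts, and leaving out each labelled sample. Depth sets how many cells show a marker: the share of cells with at least 2 cycling cell markers was 0.975% at 1000 UMIs per cell, against 3.57% at full depth. Rare classes rest on few cells, such as 55 B cell-like and 121 endothelial-like cells.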

Other observations

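The tests of explanations in this part were chosen after the results were seen. Some genes and lists not compared above also differed between libraries. Bax, a p53 target that promotes cell death, was at 95.2, 93.5, 96.8, 173, 179 and 178 CPM in microglia-like cells from library 1 to 6. Ccng1, a cyclin gene induced by p53, was at 81.5, 31.6, 34.4, 209, 115 and 251 CPM there. Senescence and secretory genes gave -0.74, -0.86, 0.22, 0.14, 0.57 and 0.82 in microglia-like cells (9 members) and -0.83, -0.72, -0.11, 0.81, 0.55 and 0.69 in astrocyte-like cells (6 members). Other lists ranged no more than random lists do: lysosomal genes by 0.28 (percentile 54.5) and glycolysis genes by 0.31 (41.8) in microglia-like cells, and astrocyte homeostatic genes by 0.20 (54.1) in astrocyte-like cells. Spp1, the osteopontin gene, was at 11.3 CPM in microglia-like cells of library 3 and at 0 to 0.0947 CPM in those of the other libraries.

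Some values fell into separate clusters of libraries, and no condition was read from this. Cdkn1a in astrocyte-like cells was at 2.30, 1.21 and 2.33 CPM in libraries 1, 2 and 3, and at 39.4, 46.0 and 44.7 CPM in libraries 4, 5 and 6. Phlda3 in microglia-like cells was at 1.04, 1.65 and 0.896 CPM in the former and at 56.8, 87.0 and 115 CPM in the latter. The p53 list in microglia-like cells was -0.47, -0.56 and -0.45 against 0.33, 0.61 and 0.58, and the share of microglia-like cells 80.6%, 77.6% and 73.9% against 20.4%, 17.2% and 8.36%. The microglia-like cells of these libraries were in different clusters, with 107, 161 and 8 of those in libraries 1, 2 and 3 in cluster 5, against 1428, 1137 and 434 in libraries 4, 5 and 6, most of theirs. Astrocyte-like cells were in different clusters in part, with 1140 of library 3 in cluster 8 and 915 of library 4 in cluster 9. Mdm2 in astrocyte-like cells had the same order but differed little, with 30.2, 29.0 and 31.8 CPM against 32.0, 32.2 and 33.2 CPM, and the counting intervals overlapped. Astrocyte homeostatic genes separated in microglia-like cells too, with -0.39, -0.26 and -0.80 against 0.89, 0.29 and 0.27, and so did the share of astrocyte-like cells, with 9.99%, 15.7% and 15.9% against 50.3%, 30.2% and 38.0%. The split was not particular to p53 targets. Reactive astrocyte genes in microglia-like cells gave -0.62, -0.18 and -0.26 in libraries 1, 2 and 3, against 0.16, 0.19 and 0.36 in the others. Ribosomal protein genes there gave -0.03, -0.42 and -0.56 against 0.30, -0.02 and 0.39. The interferon and disease-associated lists separated there too, while the lysosomal and NF-kB lists did not. How many genes split in this way was not counted. C1qa, a gene of myeloid cells, was at 277, 331, 298, 470, 178 and 106 CPM in astrocyte-like cells from library 1 to 6. RNA of other cells was not estimated, so its part in these values, those of Cdkn1a included, stays open.

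Clusters 1 and 13, with Lyz2 and Clec7a high and Sall1 low, held 2, 1 and 1 cells in libraries 1, 2 and 3 and 1703, 2915 and 2409 in libraries 4, 5 and 6. T or NK, B cell and neutrophil-like cells numbered 79, 109 and 497 in libraries 1, 2 and 3, and in libraries 4, 5 and 6 at most 9.34 for each 100 cells of these clusters. This argues against blood left in the vessels as the main source, if these classes are as frequent in it as the cells of the clusters. Monocytes were not among the classes counted and the make-up of the blood was not measured, so monocytes from blood stay open. The median UMIs of cells of clusters 1 and 13 were at most 0.877 of those of microglia-like cells in the same library, which argues against doublets of microglia as most of these cells. A median cannot exclude that some of the cells were doublets. A response to dissociation may contribute and cannot be told apart, because leaving its genes out moved nothing: 97.67% of neighbours stayed within the clusters, against 97.66% with all variable genes. Irradiation was not tested, since no library is tied to a sample.

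Microglia-like cells of library 3 formed clusters 4 and 6, with P2ry12 among the leading genes of cluster 4 and Ccl2, Cd83 and Tnf among those of cluster 6. Among equal draws of 449 cells per library, 95.01% of their neighbours came from library 3, where 16.7% would in mixed libraries. Lower depth was excluded as the explanation, since with every cell at 1000 UMIs the share was 78.25%, against 21.2% to 43.9% for the others, while a response to dissociation cannot be told apart, as leaving its genes out gave 94.68%. A shift of the whole library is a candidate explanation: across 4550 genes, the differences of library 3 from the median of the others in microglia-like and astrocyte-like cells had a Pearson r of 0.649, against 0.172 to 0.368 for the others, and genes are not independent replicates. Whether handling, sequencing, the animal or irradiation set library 3 apart was not tested.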
